A study of Mus musculus with 2 samples.

How the data were processed

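The series measured open chromatin by DNase-seq in 2 libraries of mouse liver, labelled as biological replicates 1 and 2 of 1 group. Per the labels both come from the same strain and donor record and from different tissue samples, and the age, stage and sex were not recorded. Nothing states whether the tissue came from 1 animal or several, so values with n = 2 measure the spread between these 2 libraries.

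Each replicate had 4 deposited files of results. Per the labels the build is mm10. The deposited list of each sample's files derives them from the alignments of that sample, so peaks were called per sample and not on pooled reads. The aligner, the peak caller and their versions are not given in the sources used here. The deposited false discovery rates (q-values, treated as p-values) give the FDR of the cut density for each run of bases, listed where it is under 0.05. The deposited footprints all have the value 0.01, which was read as a threshold p-value, so they could not be ranked. The 2 deposited peak lists give each peak a height, a signal that was read here as scaled to sequencing depth, which the sources used here do not state. On chromosome 19 the lowest FDR inside every peak of the stricter list was under 0.001, and in the more permissive list under 0.05. The stricter list was used except where the other is named.

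The heights of each replicate went in steps, 0.00419 in replicate 1 and 0.00439 in replicate 2. Of the 149110 and 124151 heights of the more permissive list under 1000 steps, 100% were within 0.02 of a whole number. The step was read as 1 tag, which gives the number of tags at a peak. The scale of the heights and the read totals are not stated in the labels, so the library sizes are unknown. Tags are not independent molecules, so counting intervals cover counting error only, and they are at the 95% level. FDR under 0.05 covered 48.3 Mb in replicate 1 and 40.6 Mb in replicate 2.

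Genes and transcription starts were those of the basic set of GENCODE M21, and sequence came from GRCm38. All coordinates of the files lay inside the chromosome lengths of that build. The 21 chromosomes used were the autosomes, X and Y. A peak was shared when it overlapped a peak of the other replicate by at least 1 base. A peak found in both replicates is a peak of replicate 1 that does so. Promoters were the 500 bases on each side of any annotated start, and a gene was open when both replicates had a peak there. The height of a promoter is that of its tallest peak. How uniquely reads map, for example in duplicated genes, was not examined. A missing peak therefore does not by itself mean closed chromatin. Genes said to have no peak had none in the stricter list, and some of them had one in the more permissive list. The peak lists hold 568 and 372 peaks that overlap their neighbour, and the overlap counts allow for this.

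The 27 gene lists and 34 motifs were fixed before the data were examined. Lists were tested against all other protein-coding genes with a two-sided Fisher's exact test, and peaks within 10000 bases of a gene against 10000 random lists of genes of like length, in 10 equal groups by length. Of 435 distinct listed genes 431 were protein-coding genes of the annotation. p-values were adjusted by Benjamini-Hochberg over the lists, and they describe these libraries, since genes are not replicates. Motif matches were counted on both strands by their midpoint, inside footprints and in the other bases of the same replicate's peaks, with a count of 0.5 added for ratios. Footprints outside the peaks were counted too, except in the alternative with footprints inside peaks only. The test was a two-sided Fisher's exact test of matches of the consensus and of the consensus written backwards, adjusted over the 26 motifs with such a control. Writing a consensus backwards keeps its bases but can lose a CpG, as for ETS, the E-box and CREB-ATF. It can also gain one, as for CTCF, NFI, REST, CEBP, OCT and MYOD. Some of these controls had few matches. In replicate 1 the backwards consensus of CTCF had 5 in footprints and 6 in peak bases outside them, and that of NFI had 20 and 36. The control does not correct for a lost or gained CpG. A motif was called when the adjusted p was under 0.05 in both replicates with the same direction. The 7 palindromes had no control as planned. A palindrome written backwards is in fact its complement and not itself, so a version that tests them was added as an alternative. Log2 ratios between replicates have no p, because there is 1 library on each side, and are given as percentiles among 10000 random lists of genes of like height, in 10 equal groups by height.

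Random lists of like promoter CpG came from 10 equal groups of the ratio of observed to expected CpG within 500 bases of the gene's 5' end, and 3 further lists of blood cells were added after the data were seen. The text names, for each list, the 3 members with the highest promoter rank, members of hepatocyte or ubiquitous lists with no promoter peak (the first 4 in the order of the list), open members of lists of absent cells (up to 4), the 10 genes with the tallest promoters, the 10 with the most peaks and the 5 tallest peaks of each replicate with no overlap in the other. Some members that this rule gives are not reported here. Names outside this rule are said to be chosen after their values were seen.

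The alternatives covered stricter and more permissive peak lists, reciprocal overlap of 50%, promoters of 2000 bases, flanks of 50000 bases, autosomes only, distal peaks (over 1000 bases from a start), footprints extended by 5 bases, a background within 100 bases of footprints, no motif control, matched random lists, and each replicate left out. The work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with random numbers from seed 1. The statistics were tested on simulated data: overlaps and motif positions had 0 errors against plain searches, and of 200 simulated lists of 20 genes with 20% open promoters Fisher's exact test called 99.5%, against 3% of unchanged lists. Random lists called 99.5% of lists with 3 more peaks a gene and 1.5% of unchanged ones.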

Results

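DNase-seq maps open chromatin by sequencing the ends of fragments that the nuclease DNase I cuts from nuclei, so a peak marks a stretch of DNA that the enzyme could reach and a footprint marks a short stretch inside open chromatin that was cut less than its surroundings. The series held 2 libraries from mouse liver tissue of a C57BL/6 substrain, labelled as biological replicates 1 and 2. Age, developmental stage and sex were not recorded, and both labels pointed to the same donor record with different tissue samples. There was 1 group, so the comparisons were between the 2 replicates and between sets of genes or motifs within them. Read totals were not given. Peak heights under 1000 steps were whole multiples of 1 step per library within 0.02, and with that step read as 1 tag the median peak rested on 263 tags in replicate 1 and 269 in replicate 2. Coordinates are on mouse build mm10 (GRCm38) with GENCODE M21 genes, counted from 1.

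Liver chromatin was open at 105812 peaks in replicate 1 and 88173 in replicate 2, and nearly every tall peak of either replicate was present in the other. The peaks covered 18.99 Mb in replicate 1 and 15.7 Mb in replicate 2, and their median width was 180 bases in both. The mean number of peaks was 96992.5 ± 12472.7 (SD, n = 2). Of the peaks of replicate 1, 75.4% overlapped a peak of replicate 2 by at least 1 base, and of the peaks of replicate 2, 90.5% overlapped a peak of replicate 1. After 20 shuffles within chromosomes these shares were 1.31% and 1.56%. The shared part depended on height. In the lowest 10% of the peaks by height the share was 22.5% in replicate 1 and 55.7% in replicate 2, and in the highest 10% it was 99.8% and 99.9%.

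**Figure D1:**
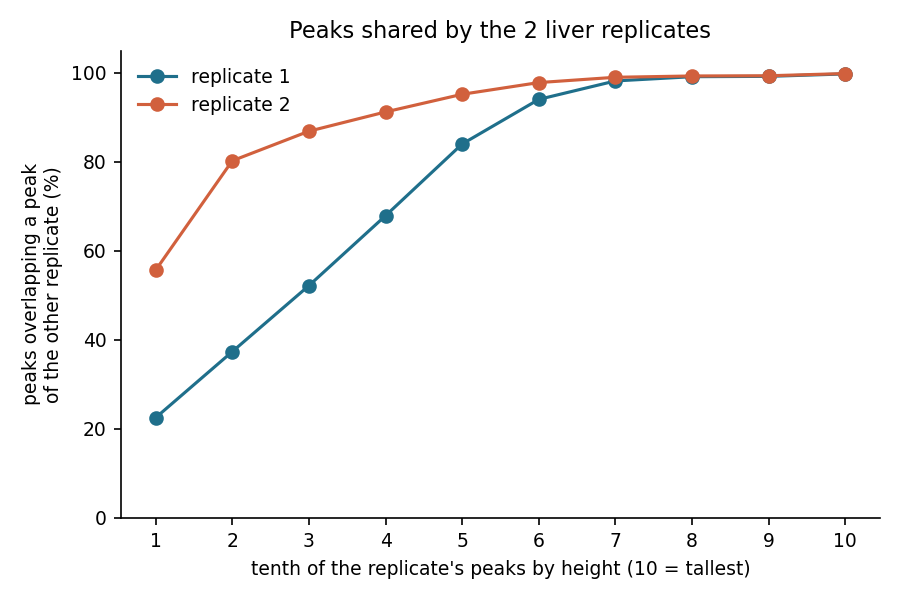
Percentage of peaks that overlap a peak of the other liver replicate (vertical axis) for 10 equal groups of a replicate's peaks by height (horizontal axis, 10 is the tallest), with 1 line per replicate. Sharing goes from 22.5% to 99.8% in replicate 1 and from 55.7% to 99.9% in replicate 2.

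The peaks that both replicates had were also ordered alike. Over 79835 overlapping pairs, the rank correlation of peak height across peaks was 0.954 (Spearman's rho) and the correlation of log2 heights was 0.970 (Pearson's r), given with no p because peaks are not independent replicates. Calculated within each autosome, rho lay between 0.945 and 0.962. For 97.9% of the pairs the heights differed by at most 2-fold. The spread of the log2 ratio exceeded what counting tags allows: in the tallest 10% its SD was 0.27 and the counting SD 0.03. The ratio also depended on height. The median log2 ratio of replicate 2 over replicate 1 was -0.17 in the lowest 10%, -0.27 in group 3 of the 10 and 0.24 in the tallest 10%, and the ratios of gene lists were therefore compared with those of peaks of like height, while heights of single genes are given as they were.

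Open chromatin was concentrated at the starts of genes. Of the peaks found in both replicates, 27.3% (95% Wilson interval 27.0 to 27.6) had their midpoint within 500 bases of an annotated transcription start, a class that holds 2.28% of the bases, which is an 11.96-fold excess. Exons outside promoters held 5.47% of the peaks, introns 39.9% and intergenic sequence 27.4%, against 3.22%, 41.2% and 53.3% of the bases. Over all peaks of a replicate, promoters held 23.4% in replicate 1 and 26.0% in replicate 2. The Wilson interval takes peaks as independent draws, so it does not measure the spread between replicates. Promoters made up 75.8% of the tallest 10% of peaks in replicate 1 and 81.0% in replicate 2. With promoters taken as 2000 bases on each side of a start the promoter share was 42.3%.

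The tallest promoter peaks belonged to genes of mixed function, and no theme among them was tested. The highest was shared by Nudt6 and Spata5, a pair of neighbours on chromosome 3, where the peak of replicate 1 ran from 37419721 to 37419880 and the height was 90.6 ± 18.2 (SD, n = 2). The promoter shared by Mplkip and Sugct on chromosome 13 reached 90.4 ± 18.8. Fzr1, an activator of the anaphase-promoting complex, reached 81.5 ± 14.4, Eloa, an elongin subunit that aids RNA polymerase II, 81.1 ± 15.7, Hjurp, the chaperone that loads the centromeric histone CENP-A, 80.2 ± 2.61, and Nup107, a nuclear pore protein, 78.6 ± 12.6. Malt1, a signalling protease of lymphocyte activation, reached 74.6 ± 18.1 and Esrra, a nuclear receptor of energy metabolism, 72.3 ± 15.04. All of these heights were averaged over both replicates.

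Among genes with a liver function, most promoters of transcription factors were open and most promoters of cytochromes P450, acute phase proteins and bile acid genes were not. Both libraries also held tall erythroid promoters, such as Slc4a1 at 13.6 in replicate 1 and 24.8 in replicate 2. The shares therefore describe the tissue and not hepatocytes alone. Across all 21911 protein-coding genes, 62.9% had a promoter peak in both replicates. Of the liver transcription factors 18 of 20 did (log2 odds ratio 2.13, adjusted p = 0.0199, two-sided Fisher's exact test), led by Ppara, the fatty acid sensor, at 7.13 ± 0.195 (SD, n = 2), Onecut2 at 6.64 ± 0.282 and Cebpa, a driver of hepatocyte differentiation, at 6.21 ± 0.349. The 2 members with no peak in the stricter list were Nr1i2 and Nr1i3, the xenobiotic sensors PXR and CAR. In the more permissive list Nr1i2 had 0.540 in replicate 1 and 0.510 in replicate 2, and Nr1i3 had 0.469 in replicate 1 alone. This call ended when only the 5' end of each gene counted (log2 odds ratio 0.96, adjusted p = 0.238, Fisher's exact test), with promoters of 2000 bases (18 of 20 open, log2 odds ratio 1.90, adjusted p = 0.0548) and among peaks above the median height (log2 odds ratio 0.03, adjusted p = 1). The share was lower for cytochromes P450 and drug metabolism (4 of 20, adjusted p = 0.000791), acute phase proteins (2 of 14, adjusted p = 0.000895), bile acid synthesis and transport (4 of 16, adjusted p = 0.00656) and female-biased liver genes (4 of 20, adjusted p = 0.000791), all by Fisher's exact test. The bile acid call ended with the more permissive peak list (adjusted p = 0.108) and without replicate 2 (adjusted p = 0.177), both by Fisher's exact test. Por, the electron donor of all microsomal P450s, had a height of 39.8 ± 7.63, whereas Cyp1a2, Cyp2b10, Cyp2c29 and Cyp2c37 had no promoter peak in either replicate. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, Cyp8b1, Baat and Slc27a5 had none either, and Hsd3b7, another enzyme of that pathway, reached 9.85 ± 2.20. In the acute phase list Saa1, Saa2, Saa3 and Hp had no peak and Lbp, the lipopolysaccharide-binding protein, reached 3.89 ± 0.266.

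The calls of these 4 lower lists ended against random lists of genes with like promoter CpG, a background chosen after seeing the data. The median ratio of observed to expected CpG in their promoters was 0.136 for the cytochromes, 0.141 for the acute phase, 0.153 for the female-biased and 0.227 for the bile acid list, and 0.764 for the ubiquitous genes. The cytochrome list had 20% open promoters and its matched lists a median of 20% (adjusted p = 1, permutation test with 10000 random lists), and the adjusted p of the same permutation test was 1 for the acute phase, 0.752 for the female-biased and 0.809 for the bile acid list. Against all other genes 14 of the 27 lists were called, 4 higher and 10 lower, and 16 had an unadjusted p under 0.05. With the matching 6 were called. The hepatocyte secreted proteins were then open more often than matched genes (75% against a median of 35%, adjusted p = 0.00135, permutation test), and so were the liver transcription factors (90% against 65%, adjusted p = 0.0099). The unadjusted p of the secreted proteins was 0.0002, the smallest that 10000 random lists can give in this permutation test, and it was the same for the stellate, germline and homeobox lists.

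Promoters of the secreted proteins of hepatocytes were open in 15 of 20 genes (adjusted p = 0.437, Fisher's exact test) and had a median height of 1.03 in replicate 1 and 0.962 in replicate 2. The direction of this list against all other genes depended on the threshold. It was higher with the more permissive peak list (log2 odds ratio 4.32, adjusted p = 0.00189, Fisher's exact test) and without replicate 2 (2.79, adjusted p = 0.00826), and lower among peaks above the median height (-1.74, adjusted p = 0.0178). Trf, the iron carrier transferrin, reached 2.44 ± 0.0308 (SD, n = 2), Rbp4, the retinol carrier, 2.24 ± 0.118 and Apoa2 1.99 ± 0.339. Alb, the gene of serum albumin on chromosome 5 from 90460897 to 90476602, had no promoter peak in the stricter list, and in the more permissive list it had 0.528 in replicate 1 and 0.431 in replicate 2. In the list of cholesterol and fatty acid metabolism 15 of 20 were open (adjusted p = 0.437, Fisher's exact test). Acadm, a dehydrogenase of fatty acid oxidation, reached 40.1 ± 3.98, Hmgcs1 of cholesterol synthesis 37.8 ± 6.20 and Srebf2, the sterol-sensing transcription factor, 36.6 ± 9.76. Acaca, Acacb and Fabp1 had no peak in the stricter list. In the more permissive list Acacb had 0.608 in replicate 1 and 0.554 in replicate 2, and Acaca had 0.272 in replicate 1 alone. Of the urea cycle and amino acid genes 12 of 20 were open (adjusted p = 0.884, Fisher's exact test). The glutaminase Gls2 reached 29.9 ± 1.19, Slc25a15 12.8 ± 0.410 and Cth 11.7 ± 0.469. Cps1, Arg1, Tat and Hpd had no peak in the stricter list. In the more permissive list Hpd had 0.742 in replicate 1 and 0.664 in replicate 2, and Arg1 had 0.528 and 0.281. Of gluconeogenesis and glycogen genes 9 of 14 were open (adjusted p = 1, Fisher's exact test), with Pcx at 34.0 ± 7.20, Khk at 20.5 ± 0.626 and Pygl at 11.1 ± 0.517, and with no peak at G6pc, Fbp1 and Slc2a2.

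Lists of zonation and of sex bias did not pass the test except for the female-biased list above. Of the pericentral genes 10 of 12 were open (adjusted p = 0.328, Fisher's exact test), with the aminotransferase Oat at 28.6 ± 3.08 (SD, n = 2), the glutamine synthetase Glul at 23.8 ± 5.78 and Rnf43, an inhibitor of Wnt signalling, at 9.52 ± 2.65, and with no peak at Cyp2e1 or Cyp1a2. Of the periportal genes 4 of 12 were (adjusted p = 0.107, Fisher's exact test), led by Gls2, Ass1 at 5.43 ± 0.553 and Aldh1b1 at 5.02 ± 0.683, and with no peak at Cyp2f2, Hal, Sds or Hsd17b13. Of the male-biased genes 8 of 20 were open (adjusted p = 0.0689, Fisher's exact test, 0.0319 with promoters of 2000 bases and 0.0178 among peaks above the median height), with Nudt7 at 17.8 ± 1.71, Gstp1 at 11.5 ± 0.649 and Cyp2u1 at 5.53 ± 0.650, and with no peak at Cyp2d9, Cyp4a12a, Cyp4a12b or Hsd3b5. The open female-biased promoters included Trim24 at 30.9 ± 10.3, Abcd2 at 3.52 ± 0.473 and Cux2 at 1.65 ± 0.0869, while Cyp2b9, Cyp2b13, Cyp3a41a and Cyp3a44 had no peak. Of the fetal and oncofetal genes 8 of 11 were open (adjusted p = 0.851, Fisher's exact test). Igf2bp3, an RNA-binding protein of embryonic tissue, reached 23.6 ± 3.41, Tspan8 7.35 ± 2.20 and the imprinted gene Peg3 4.95 ± 0.100, and Hba-x, an embryonic globin, had no peak in the stricter list and 0.461 in replicate 2 alone in the more permissive list. Named after their values were seen, Afp, the fetal serum protein, and Hbb-y, another embryonic globin, had a peak in replicate 2 alone, at 1.29 and 0.668.

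Genes in use in nearly all cells had open promoters. All 20 ubiquitous genes were open (adjusted p = 0.000588, Fisher's exact test), with the transferrin receptor Tfrc at 43.0 ± 10.1 (SD, n = 2), the ribosomal protein gene Rpl3 at 35.0 ± 4.14 and Vcp at 33.4 ± 4.15. Of the circadian clock genes 18 of 20 were (adjusted p = 0.0199, Fisher's exact test), with the repressors Cry2 at 41.7 ± 10.8 and Per1 at 30.1 ± 4.84 and the transcription factor Tef at 34.3 ± 3.23. Neither call held against random lists of like promoter CpG (adjusted p = 0.113 for the ubiquitous and 1 for the clock genes, permutation test), and with the more permissive peak list the clock call ended too (adjusted p = 0.0599, Fisher's exact test).

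Of the lists for cells that share the liver with hepatocytes, the stellate list was open in full, and few promoters of the macrophage and lymphocyte lists were open. All 16 stellate genes were open (adjusted p = 0.00245, Fisher's exact test), with Reln at 9.16 ± 2.80 (SD, n = 2), Nes at 2.86 ± 0.719 and Lhx2 at 2.66 ± 0.336. Against lists of like promoter CpG the stellate share of 100% stood beside a median of 62.5% (adjusted p = 0.00135, permutation test), and among peaks above the median height the call ended (log2 odds ratio -0.24, adjusted p = 0.869, Fisher's exact test). Of the macrophage and Kupffer cell genes 2 of 16 were (adjusted p = 0.00032, Fisher's exact test), namely Cd68 at 1.63 ± 0.248 and Laptm5 at 1.18 ± 0.215, and of the lymphocyte genes 1 of 15 (adjusted p = 0.000122), which was Cd3g at 1.12 ± 0.199. The calls of the lymphocyte and the macrophage list ended with matching on promoter CpG (adjusted p = 0.13 and 0.866, permutation test). The sinusoidal endothelium had 9 of 16 open (adjusted p = 0.716, Fisher's exact test), led by the growth factor receptor Kdr at 4.01 ± 0.838, Maf at 3.10 ± 0.505 and Eng at 1.66 ± 0.202, and cholangiocytes had 8 of 16 (adjusted p = 0.415), led by Sox4 at 6.79 ± 0.544, Elf3 at 1.97 ± 0.343 and Sox9 at 1.91 ± 0.0584. Among peaks above the median height the endothelial and the cholangiocyte list were called lower, with 3 of 16 open each (adjusted p = 0.00897, Fisher's exact test).

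Erythroid promoters were taller in replicate 2 than in replicate 1. Of 11 erythroid genes 9 were open in both replicates (adjusted p = 0.328, Fisher's exact test), against a median of 27.3% for lists of like promoter CpG (adjusted p = 0.00216, permutation test with 10000 random lists). Slc4a1, the anion exchanger of the red cell membrane, lies on chromosome 11 from 102348824 to 102366203 and reached 13.6 in replicate 1 and 24.8 in replicate 2. Tal1, a transcription factor of blood formation, reached 10.9 and 14.6. Named after their values were seen, the adult beta globin gene Hbb-bs had 5.30 and 10.4 and the erythroid regulator Gata1 6.05 and 10.3, while Hba-a1 had a peak of 0.835 in replicate 2 alone and Hba-a2 had none. The height was greater in replicate 2 for 9 of 9 open promoters, with a median log2 ratio of 0.87, where random lists of like height had a median of 0.01 and the list lay at percentile 100 of 10000. With 1 library on each side this describes these libraries and carries no p. Distal peaks around the same genes went the same way, with 53 of 66 taller in replicate 2, a median log2 ratio of 0.24 and percentile 100 among peaks of like height. Distal peaks of the fetal list, which holds 2 globin genes, lay at percentile 97.3. Hepatocyte lists lay on both sides, among them secreted proteins at 3.32, liver transcription factors at 80.1 and cholesterol and fatty acid metabolism at 93.1, and the neuron list lay lowest of all lists at 0.26.

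**Figure D2:**
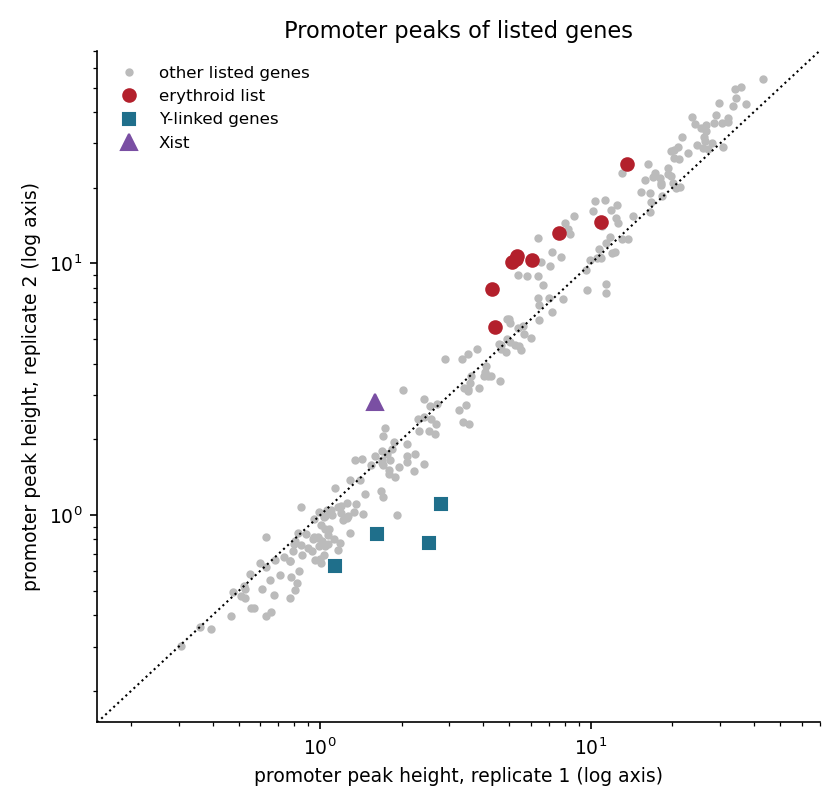
Promoter peak height in replicate 1 (horizontal log axis) and in replicate 2 (vertical log axis) for listed genes with a peak in both, where the dotted line marks equal heights. The 9 erythroid promoters and Xist lie above the line, and the 4 Y-linked promoters lie below it.

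In 4 of the 6 lists of cells absent from liver few promoters were open. The share was lower for muscle (3 of 16, adjusted p = 0.00119, Fisher's exact test), pancreas (3 of 15, adjusted p = 0.00236), germline (2 of 16, adjusted p = 0.00032) and epidermis (1 of 16, adjusted p = 9.62e-05), and embryonic homeobox genes (6 of 16, adjusted p = 0.0689) and neuron genes (10 of 16, adjusted p = 1) did not pass. Among peaks above the median height both of these were called lower, with 3 of 16 open each (adjusted p = 0.00897, Fisher's exact test), and the homeobox genes also when only the 5' end of each gene counted (adjusted p = 0.018). The germline list was low against genes of like promoter CpG as well (12.5% against 56.3%, adjusted p = 0.00135, permutation test), as were the homeobox genes (37.5% against 87.5%, adjusted p = 0.00135), while the muscle, pancreas and epidermis calls ended (adjusted p = 0.17, 0.0856 and 0.195). The open members included the germline genes Tex14 at 23.3 ± 4.32 (SD, n = 2) and Dazl at 13.8 ± 1.96, the myosin light chain Mylpf at 13.6 ± 1.31, the pancreatic transcription factors Bhlha15 at 5.07 ± 0.496 and Nkx6-1 at 4.94 ± 0.0971, and the keratin Krt10 at 4.65 ± 0.292. Others were the glutamate receptor subunit Grin1 at 2.92 ± 0.878, the vesicular glutamate transporters Slc17a7 at 1.91 ± 0.266 and Slc17a6 at 1.46 ± 0.654, Dlx2 at 1.33 ± 0.176, Cela1 at 1.07 ± 0.0305, Actn3 at 0.900 ± 0.161 and Myog at 0.604 ± 0.0706, and the homeobox genes Pax6 at 2.00 ± 0.572 and En1 at 1.01 ± 0.0280.

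**Figure D3:**
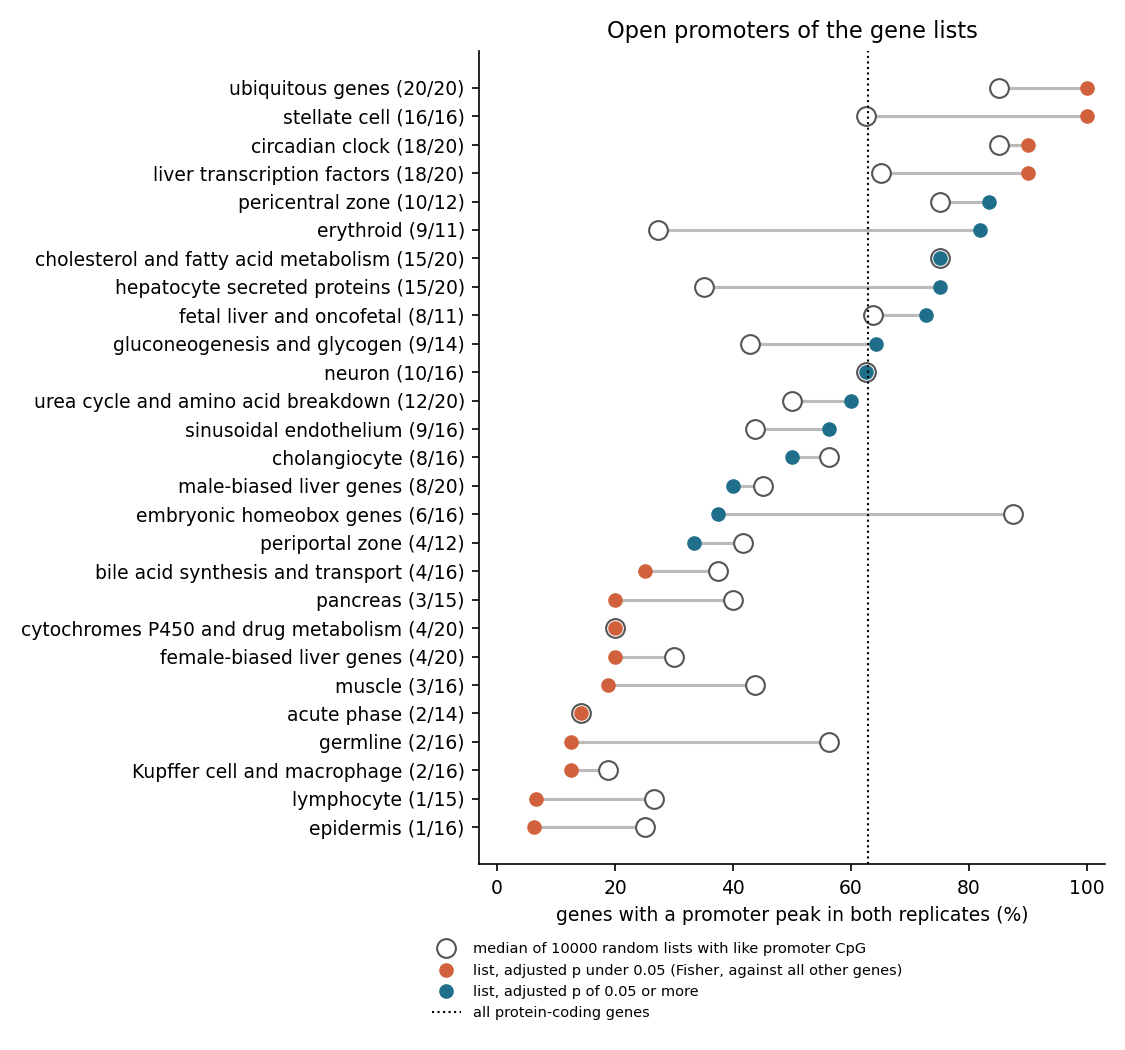
Percentage of genes with a promoter peak in both replicates (horizontal axis) for the 27 gene lists, with open circles for the median of 10000 random lists of like promoter CpG and a dotted line for all protein-coding genes. The lists run from 6.25% for epidermis to 100% for the ubiquitous and stellate lists.

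The random lists for counts around genes were matched on gene length and not on how uniquely reads map. Counting all peaks within 10000 bases of a gene set the female-biased list apart. Its median was 0 peaks per gene against 4 in random lists of the same gene lengths (adjusted p = 0.0054, permutation test with 10000 random lists), and 8 lists had an unadjusted p under 0.05 but no other passed the adjustment. The erythroid genes had a median of 6 against 2 (adjusted p = 0.0864, permutation test), the ubiquitous genes 6 against 3 (adjusted p = 0.0783), the cytochromes P450 1 against 3 and the bile acid genes 1 against 3.5 (adjusted p = 0.0864 for both). The female-biased call ended against random lists matched on promoter peaks too (adjusted p = 0.549, permutation test) and with distal peaks alone (adjusted p = 0.153), where the erythroid list was called instead (median 4 against 1, adjusted p = 0.027). Without replicate 1 there were 2 calls, the erythroid list being added, without replicate 2 there were 3, the cytochrome and male-biased lists being added, and 6 lists passed on the autosomes alone. The genes with the most peaks were Gm20388 with 497 and Fgfr2 with 153, both with an annotated span of several megabases, followed by Gse1 with 86, the calmodulin-binding transcription factor Camta1 with 65, the phosphodiesterase Pde4d with 52, Zfpm1, the GATA1 cofactor FOG1, with 51, Gm37240 with 42, the NFI family member Nfic with 41, Nav2 with 39 and Zmiz1 with 38. Zfpm1 held its peaks in 75.1 kb, whereas Camta1 spanned 965 kb.

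Footprints numbered 475897 in replicate 1 and 395116 in replicate 2, a mean of 435506 ± 57120.8 (SD, n = 2), with a median width of 11 bases in both. They lay in the peaks of their own replicate in 65.0% and 65.1% of cases, and 91.5% and 91.4% of the peaks held at least 1. Of the footprints of replicate 1, 56.2% overlapped a footprint of replicate 2, and 69.4% the other way. After shifting the footprints by 50 bases these shares were 34.0% and 41.1%, against which the overlap is to be read.

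Footprints were rich in sites of CTCF, NFI and REST and poor in sites of FOXA. Matches of CTCF, the insulator protein, were denser in footprints, inside peaks or not, than in peak bases outside footprints. The difference was 6.14 ± 0.45 on the log2 scale (SD, n = 2) after subtracting the same ratio for the consensus written backwards (higher adjusted p of both replicates 1e-07, two-sided Fisher's exact test). The value was 3.79 ± 0.44 for NFI (adjusted p = 4.45e-12), 2.91 ± 0.67 for REST, the repressor of neuronal genes (adjusted p = 2.45e-05), 1.32 ± 0.27 for the hepatocyte regulator HNF4A (adjusted p = 0.00891), 1.11 ± 0.18 for NRF1 (adjusted p = 1.38e-07), each by Fisher's exact test. For ETS factors it was 1.43 in replicate 1 and 0.76 in replicate 2 (adjusted p = 1.04e-08, Fisher's exact test). RUNX (0.49 ± 0.11) and NFY (0.31 ± 0.04) were also called. NEUROD was called at 1.58 ± 0.14, but its consensus can lie inside that of CTCF. With matches near a CTCF match left out it was 1.19 and still called, an alternative added after seeing the data. Its matches in footprints of replicate 1 then went from 1631 to 1174. The 5 motifs called lower in footprints were FOXA, the pioneer factor of liver, at -1.23 ± 0.01 (adjusted p = 1.23e-34, Fisher's exact test), the T-box at -0.71 ± 0.19, the D-box at -0.69 ± 0.06, PU.1 of myeloid cells at -0.41 ± 0.14 and GATA at -0.30 ± 0.07.

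In all, 14 of 26 tested motifs were called in both replicates with the same direction, 9 higher and 5 lower. PPAR-RXR (2.72 ± 0.82), YY1 (3.36 ± 1.73), ONECUT1 (0.74 ± 0.42), CEBP (0.29 ± 0.42) and HNF1 (0.25 ± 2.32) were not called, and HNF1 had 10 matches in footprints of replicate 1 and 8 in replicate 2. The plain log2 ratios were 2.24 and 1.84 for YY1 and 2.30 and 0.91 for PPAR-RXR. Backwards, YY1 had 2 matches in footprints of replicate 1 and 0 in replicate 2, and PPAR-RXR had 3 and 2. With so few control matches, these 2 missing calls do not show a lack of enrichment. The GATA value was 0.42 in place of -0.30 when the background was the bases within 100 bases of a footprint, and the D-box and PU.1 calls ended there and with footprints extended by 5 bases. The HNF4A call rested on the backwards control, since its plain log2 ratio was -0.23 in replicate 1, and it ended with extended footprints (adjusted p = 0.312, Fisher's exact test) and with footprints inside peaks only (adjusted p = 0.088). With no control NFY and RUNX turned to -0.23 and -0.47. The E-box was not called over all footprints, with 0.97 in replicate 1 and -0.08 in replicate 2. Away from transcription starts 8 motifs were called, among them the E-box (0.78, with 1.12 in replicate 1 and 0.44 in replicate 2). Calls that ended there with values of much the same size were HNF4A (1.22, adjusted p = 0.0504, Fisher's exact test), RUNX (0.47, adjusted p = 0.0504, Fisher's exact test), and NRF1 (0.95), while the D-box had -0.55, ETS 0.66 and NFY 0.04, and CTCF was not called either. CTCF had 5982 matches in those footprints of replicate 1, but its backwards consensus had 1 match in total there, too few for the test. Sites that read the same on both strands had no such control and their plain log2 ratios were 2.15 ± 0.53 for CREB-ATF, -0.40 ± 0.10 for STAT5-BCL6, -0.23 ± 0.08 for AP-1, -0.26 ± 0.13 for MYOD, -0.46 ± 0.29 for GRHL, -1.07 ± 0.05 for MEF2 and -1.39 ± 0.32 for the glucocorticoid receptor. Tested against the backwards consensus after all, an alternative added after seeing the data, STAT5-BCL6 turned to 0.45 and AP-1 to 0.37, and the glucocorticoid receptor had 0.44 (adjusted p = 0.556, Fisher's exact test). SP-KLF sites, which read the same backwards, had 3.67 ± 0.08.

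**Figure D4:**
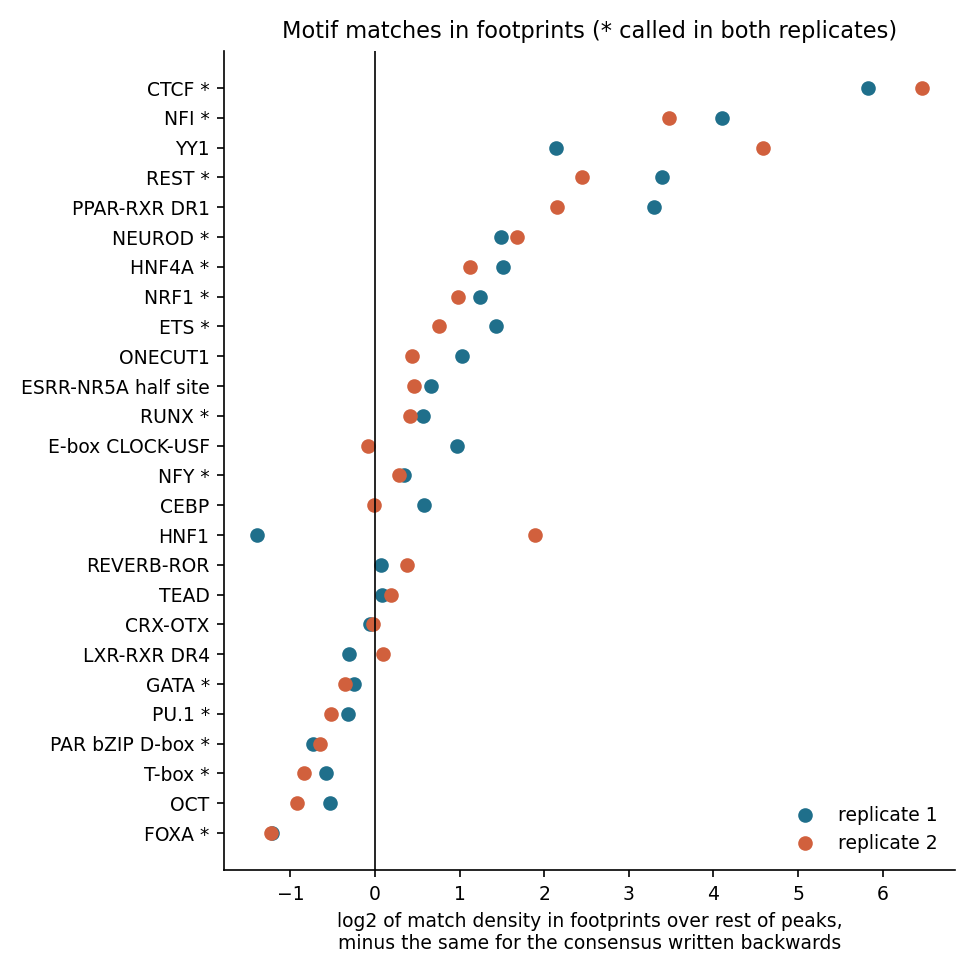
Log2 ratio of motif match density in all footprints over the peak bases outside footprints, minus that of the consensus written backwards (horizontal axis), for the 26 tested motifs in each replicate, with an asterisk at the 14 motifs called in both. CTCF lies at 5.83 and 6.46 and FOXA at -1.22 and -1.23.

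Peaks of 1 replicate only were mostly low. There were 25977 in replicate 1, 24.6% of its peaks, and 8396 in replicate 2, 9.52%. Their median height was 0.520 and 0.466, against 1.58 and 1.34 for the other peaks, and 61.3% and 55.5% overlapped a peak of the other replicate's more permissive list. On the X chromosome the shares were 24.2% and 8.87%. On the Y chromosome 8 of 31 peaks were found in replicate 1 only and 3 of 26 in replicate 2 only. The gene regions of the hepatocyte secreted proteins held 22 peaks of replicate 1 only among 83, and 4 of replicate 2 only among 66. All but 1 of the 10 tallest such peaks lay within 500 bases of a transcription start. In replicate 2 the highest was near Garem1 on chromosome 18 from 21300221 to 21300380 with a height of 39.0, followed by Fnip2 with 21.5, Dstn with 16.8, Crem with 16.1 and Sdf4 with 13.4. In replicate 1 the highest was near B4galt5 on chromosome 2 from 167349321 to 167349440 with 17.8, followed by Gatad2b with 17.4, Zc3h4 with 16.6 and Pkn2 with 16.2. Each of the 5 tallest peaks of either replicate was at most 60 bases from a peak of the other replicate.

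Genes of the sex chromosomes differed between the replicates in opposite directions, and they were chosen after their values were seen. The promoter of Xist, the RNA that silences 1 X chromosome in female cells, lies on the X chromosome and reached 1.59 in replicate 1 and 2.81 in replicate 2, a log2 ratio of 0.82 with a counting interval of 0.64 to 1.00, where shared peaks with a median height of 2.35 had a median log2 ratio of -0.24. On the Y chromosome Ddx3y went from 2.51 to 0.773, Eif2s3y from 2.79 to 1.103, Uty from 1.62 to 0.844 and Kdm5d from 1.13 to 0.628. All 9 shared peaks of the Y chromosome before 90 Mb were lower in replicate 2, with a median log2 ratio of -1.03, and 10000 random sets of like height had a median of -0.21. The 14 shared peaks of the Y chromosome from 90 Mb on had a median of -0.18, at percentile 70.6 among sets of like height. The division at 90 Mb was chosen after the data were seen.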

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

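Matching on promoter CpG, the autosome-only region test, the test of palindromes, the permissive peak count, footprints inside peaks only, the number of footprints with a replicate left out and the NEUROD value were chosen after seeing the data. No paired analysis was possible because there is 1 group. The footprints could not be reduced to their stronger part, for their number or for their overlap, because all have the value 0.01. The number of peaks was a mean of 48416 among peaks above the median height and 154542 in the more permissive list, against 96992.5. The share of footprints shared fell to a mean of 48.7% with reciprocal overlap, against 62.8%. The rank correlation was 0.925 for peaks over 1000 bases from a start, against 0.954. The promoter share of shared peaks was 42.3% with 2000 bases, 38.3% among peaks above the median height, and 23.4% to 26.0% with a replicate left out. Peaks of 1 replicate only numbered 14131 in both replicates together when the other replicate's more permissive list was used, against 34373. The promoter test called 6 lists with matching on CpG, against 14. The region test called 3 lists with 50000 bases, 6 on autosomes, 0 with lists matched on promoter peaks, and 2 to 3 with a replicate left out, against 1. Motifs called numbered 8 of 26 for distal footprints, against 14 of 26. With no control 27 of 34 were called, and these include motifs that the count of 14 did not test. Some values turned in sign and were called in the main test, in the alternative or in both. Among peaks above the median height they were the log2 odds of hepatocyte secreted proteins (-1.74) and of stellate genes (-0.24). With the background near footprints GATA turned (0.42). With no control HNF4A (-0.18), ONECUT1 (-0.42), REVERB-ROR (-0.51), NFY (-0.23), TEAD (-0.51) and RUNX (-0.47) did. With palindromes controlled STAT5-BCL6 (0.45) and AP-1 (0.37) did. Of these, only the stellate, GATA, HNF4A, NFY and RUNX values were called in the main test. The turned values of the stellate genes and HNF4A were not called. Values called in neither that turned included the glucocorticoid receptor (0.44) and MYOD (0.02) with palindromes controlled and CEBP (-0.16) with no control. Except where the setting itself removes peaks or footprints, the cause was not tested. The mean share of peaks shared was 83.0%, and it ran from 77.4% to 88.7% in the 4 alternatives tried. These lie within 1 SD of the main value, but that SD of 10.6 comes from the 2 directions of overlap. It is therefore no test of stability. The lowest 10% of the peaks was shared least, at 22.5% and 55.7%, so peaks near the threshold are the least certain.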

Other observations

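The tests of the tall replicate-only peaks were chosen before their values were seen, and the other tests here were chosen after the patterns were seen. Distal peaks, over 1000 bases from any transcription start, were compared with bases 500 to 1000 bases away from them, after subtracting the ratio of the consensus written backwards. Net of that control, CTCF matches were denser in the peaks by 7.97 ± 0.50 on the log2 scale (SD, n = 2). The value was 1.88 ± 0.18 for GATA, 1.52 ± 0.28 for NFI and 1.47 ± 0.02 for ETS factors. It was 1.38 ± 0.15 for PU.1, 1.28 ± 0.20 for HNF4A and 0.46 ± 0.01 for FOXA. The hepatocyte regulator HNF1 had 2.63 ± 0.18, on 19 matches in peaks of replicate 1 and 14 in replicate 2. Its backwards consensus had 2 in each, and its plain log2 ratios were 0.82 and 0.87. The plain log2 ratios were 0.62 and 0.84 for GATA and 3.84 and 3.89 for NFI, the reverse of the order of their net values. The backwards consensus of NFI had 17 matches in peaks of replicate 1 and 12 in replicate 2. That of GATA was itself less dense in the peaks, with log2 ratios of -1.14 and -1.17. The ETS consensus holds a CpG and its backwards form holds none. Outside the peaks of replicate 1 they had 498 and 2372 matches, so the ETS value may reflect CpG content. FOXA matches themselves were less dense in the peaks, with a plain log2 ratio of -0.54 in replicate 1 and -0.55 in replicate 2. Of the other hepatocyte motifs, CEBP (0.83 ± 0.17) and STAT5-BCL6 (0.47 ± 0.07) were called higher and the ESRR-NR5A site lower at -0.68 ± 0.14, and PPAR-RXR (0.38 ± 0.10), the glucocorticoid receptor (0.17 ± 0.05), ONECUT1 (-0.02 ± 0.05) and LXR-RXR (-0.00 ± 0.21) were not called. The motifs filed beforehand under cells absent from liver are not all confined to such cells, since Grhl2 is on the cholangiocyte list. Of these motifs, MEF2 (1.27 ± 0.00), GRHL (0.79 ± 0.01), OCT (0.74 ± 0.01), MYOD (0.63 ± 0.19) and NEUROD (0.63 ± 0.01) were called higher. A NEUROD match can lie inside a CTCF match, and CTCF matches were not left out here. T-box (-0.46 ± 0.05) and CRX-OTX (-0.41 ± 0.04) were called lower. REST (1.02 ± 0.26) was not called, although its plain log2 ratios were 3.84 and 4.01. It had 122 matches in peaks of replicate 1 and 104 in replicate 2. Its backwards consensus had 8 and 6 there, which is few for the test. The missing call therefore does not show that REST sites were no denser in the peaks. The plain log2 ratios of MEF2 (-0.20 and -0.33) and OCT (-0.48 and -0.52) were negative like those of FOXA. Of 26 further erythroid genes, listed after the data were seen, 25 had an open promoter, among them Zfpm1 at 48.7 ± 7.51, Bpgm at 27.1 ± 3.47 and the haem enzyme Fech at 26.8 ± 7.23. Of 16 megakaryocyte and progenitor genes 12 were open, led by Runx1, Lmo2 and Kit, and of 16 granulocyte and mast cell genes 5 were, led by Csf3r, Ltf and Mpo.

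Distal shared peaks of like height were ranked by their shift between the replicates, leaving out the regions of the erythroid lists. Of the 5130 peaks most shifted to replicate 2, 0.292% held a CTCF match, and of the 5120 most shifted to replicate 1, 18.0% did. AP-1 matches were in 8.97% and 3.57% of these peaks, and REST matches in 0.0585% and 0.762%. Hepatocyte motifs went both ways, with HNF4A in 0.546% and 0.215%, NFI in 1.01% and 0.410%, CEBP in 0.682% and 1.37% and ONECUT1 in 0.409% and 0.703%, and T-box matches were in 1.33% and 0.449%.

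Erythroid promoters were taller in replicate 2, where Afp (1.29) and Hbb-y (0.668) had a promoter peak as well, and distal peaks of the fetal list lay at percentile 97.3, while those of hepatocyte lists lay on both sides (3.32 for secreted proteins, 93.1 for cholesterol and fatty acid metabolism) and those of neuron genes at 0.26. A general rise of tall peaks in that library is argued against, since the list lay at percentile 100 among lists of like height. The 21 distal peaks around lymphocyte genes lay at percentile 4.48, towards replicate 1. Only 1 of 15 lymphocyte promoters was open, so these peaks may not track lymphocytes, and lymphocytes do not stand for all white blood cells. White blood cells left in the tissue are therefore not excluded. A candidate explanation is a larger share of nucleated erythroid precursors in replicate 2, as in fetal or blood-forming liver. Outside the erythroid regions, GATA matches were in 39.4% of the peaks most shifted to replicate 2 and in 16.2% of all distal shared peaks. Of the peaks most shifted to replicate 1, 6.78% held a GATA match. The ratio between these ends was 5.82, and it was 0.683 for the consensus written backwards. The list of markers was fixed beforehand, and Hbb-bs had 5.30 and 10.4 and Hba-a1 0.835 in replicate 2 alone. No sort removed such cells as far as the labels tell, and other cells use GATA sites. AP-1, HNF4A, NFI, T-box and MYOD matches were also commoner in the peaks shifted to replicate 2 (MYOD 5.83% and 3.24%). CTCF matches differed more than GATA matches. They were in 0.292% of the peaks shifted to replicate 2, 18.0% of those shifted to replicate 1 and 9.74% of all. A larger erythroid share was not shown to account for that. The age is not in the labels either, so the larger erythroid share stays a hypothesis.

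Y-linked promoters were lower and Xist was higher in replicate 2. Counting noise is argued against, since the highest upper counting bound of the 4 Y-linked log2 ratios was -0.56, below the median of -0.17 of all shared peaks and that of -0.22 of random lists of like height, and reads shared between the X and Y copies are argued against, since the log2 ratio of the Y copy to the X copy fell by at least 1.36 in each of 4 pairs (-1.36 in the smallest). Different shares of male and female tissue in the 2 libraries may account for it: without Xist, the median log2 ratio of X peaks was 0.10 above that of autosomal peaks of like height, and 0 of the 19 autosomes reached that shift, the highest being 0.02. Sex is not in the labels, so this stays a hypothesis. It needs tissue of more than 1 animal, while both labels point to the same donor record. The design has 1 group, so no biological difference that it names could be tested for these patterns.

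The tallest peaks of 1 replicate only lay beside peaks of the other. Among the 100 tallest in each replicate, 98% and 97% were within 500 bases of a peak of the other, and at least 98.4% of their bases had an FDR under 0.001 there, against 7.26% and 15.7% over all replicate-only peaks. Sites open in 1 sample only are argued against for these 100, since at least 98.4% of their bases were listed in the other replicate. This is consistent with 1 open region being divided at different places in the 2 lists, and it says nothing of the lower replicate-only peaks. Over 500 bases from any peak of the other replicate, the tallest were 4.75 on the X chromosome in replicate 1 and 4.57 on chromosome 12 in replicate 2.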
